A study of Arabidopsis thaliana with 24 samples.

How the data were processed

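Poly(A)-selected, directional libraries (NEBNext Ultra II) were made from RNA of Arabidopsis thaliana roots that had been separated by razor, per the labels' protocols. Plants grew vertically on mesh on Murashige and Skoog medium for 4 days with iron and 3 more days with or without it, per the labels' protocols. The 24 samples fell into 8 groups of 3, each group being taken from the sample labels. Per the submitters' processing notes, the TAIR10 build, FastQC, TopHat2 and edgeR were used, without versions, order or roles being stated; the counting program, its strand setting, gene lengths and filters are not given in the sources used here. RPKM values were made by the authors, per kilobase of gene and per number of library reads, and deposited for 33602 genes as 1 column per group. Low values of single-exon genes fell on steps of single reads from separate libraries, as a mean of separate libraries would; 3 distinct steps were seen in each group except iron-sufficient wild type, where 2 were. Between 71.5% and 77.8% of the low values lay within 0.2% of whole reads. The 23 distinct steps correspond to effective libraries of 14834500 to 24011400 reads, after any scaling by the authors. Values per library were not used, so no standard deviation, confidence interval or test between groups was computed from them.

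Significant genes were taken from 7 comparison tables deposited by the authors, which give a q-value for each gene listed; the test behind the q-values is not stated. All q-values listed lay under 0.05, and the listed genes differed about 1.5-fold or more between group means, by the values. The table headed PYE was matched by its values to the PPL column of the RPKM table. Of its 3 genes, PYE and CNGC12 differed in the same direction in pye-1, so the match by values rested on MRD1. A separate table was headed pye-1. A sheet of words on promoter activity was not used. Gene identifiers were matched to TAIR10.1 for symbols and coordinates, and 32835 of 33602 (97.7%) matched. No column of values was left unassigned to a group.

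Genes were kept at an RPKM of at least 1 in at least 1 group, which left 19767 genes; 6830 genes stood at 0 in every group. Differences were taken on log2(RPKM + 0.5), and fold values are plain ratios of RPKM. Of 14 comparisons, 7 had an authors' table. In the other 7, which set the 5 lines against pye-1, WER13 against WER65, and the mean of WER13 and WER65 against the mean of SHR23 and PEP45, genes differing at least 2-fold were counted without a test. The plan, made before the data were examined, had been moderated tests with limma, list tests with camera and comparisons of the resulting calls with the authors' tables; with 1 mean per group none of these could be fitted. The 20 gene lists, holding 241 genes, were fixed before the data were examined, and the core clock list, the second clock list and the list of shoot transcripts outside photosynthesis were added afterwards. For each list the members named in the authors' table were counted, and the list's median log2 difference was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression with a fixed seed, as a description of these libraries and not a test. The median number of listed genes in those random lists was taken as well. The cortex list had 3 kept genes and was not compared with random lists. The step was tested on simulated data for the comparison of PPL with iron-deficient wild type, over 19767 genes with 200 changed by 1 on the log2 scale: 20 of 20 planted lists of 10 genes lay in the top tail, and 2 of 20 unchanged lists lay in either tail.

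The overlap between pye-1 and each line was set against that of independent lists, and against 100 simulated unchanged groups sharing a control, with normal noise whose spread in each expression bin came from the middle of the differences between PPL and iron-deficient wild type. Those differences hold any real effect of PPL, so for PPL itself the simulated values are not independent. The simulated covariance was also divided by the observed spreads of pye-1 and each line. For the core clock genes alone, a standard error of each line's log2 difference from wild type was derived from the authors' q-value, read as a 2-sided normal p, and set beside the difference from pye-1, which assumes that pye-1 varied as wild type did. Named genes followed a rule fixed before the data were examined: PYE, up to 4 members of each described list with the smallest q-value, 11 iron genes in any comparison, and the 8 largest rises and falls against wild type (4 in other comparisons) among genes with an RPKM of at least 2 in the higher group. The part of that rule on overlap between replicates could not be applied. Outside the rule, and chosen after their values were seen, were VTL2 in wild type, RSL4 and ADH1 in pye-1, NAS3, MRD1, VTL2 and S8H in PPL, RSL4 and PRP3 in WER65, the root hair and xylem genes given for WER13 against WER65, where no q-values exist, the neighbours of PYE, and genes given under other observations for lines where the rule did not name them. Alternatives were pseudocounts of 0.1 and 1, no filter, a mean RPKM of at least 5, quantile normalization, centring on the median, and a 2-fold minimum; a q-value under 0.01 was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Reads of near-identical copies (LHCB1, RBCS, FRO4 and FRO5, IMA2 and IMA3) and of overlapping genes can be assigned to the wrong member.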

Results

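RNA was sequenced from roots of 7 day old Arabidopsis thaliana seedlings in 24 samples, 3 in each of 8 groups. Wild type was kept either on iron (0.1 mM FeEDTA) or, for the last 3 days, on medium without FeEDTA that held 300 µM ferrozine, a chelator that binds ferrous iron. The other 6 groups were all iron-deficient. They were pye-1, a mutant of POPEYE (PYE), which encodes a basic helix-loop-helix transcription factor of the root iron-deficiency response, and the localization lines PPL, SHR23, PEP45, WER13 and WER65. The labels give the GFP localization as V-EN-C-EP in PPL, V-EN in SHR23, C-EN-V in PEP45, EP-C in WER13 and EP in WER65, without spelling out the codes. The sample records write PYE where the series design lists pye-1, and the group is called pye-1 here. Values are RPKM, deposited as 1 mean per group, so every RPKM given is the authors' mean and no spread between replicates can be given. Differences are called a rise or a fall only where the authors' own comparison lists the gene. The smallest steps between low values corresponded to libraries of 14834500 to 24011400 effective reads.

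The PYE transcript (AT3G47640, chromosome 3, 17567126 to 17569394 in TAIR10.1) was examined first. Its authors' mean was 11 RPKM in iron-sufficient and 45.1 in iron-deficient wild type, a 4.1-fold rise (q = 6.94e-05 in the authors' deposited table). It fell to 20.6 in pye-1 (q = 0.0001 in the authors' deposited table), 2.19-fold below wild type, so transcript from the locus was still counted in the mutant. The level also fell in PPL, to 25.3, in PEP45, to 28.9, and in WER65, to 27.5. In SHR23 it was 45.8 and in WER13 30.3, neither of them listed by the authors. With similar falls in pye-1 and in some lines, the level does not check which group is the mutant. The values do not separate reads of different PYE copies in a line.

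**Figure D1:**
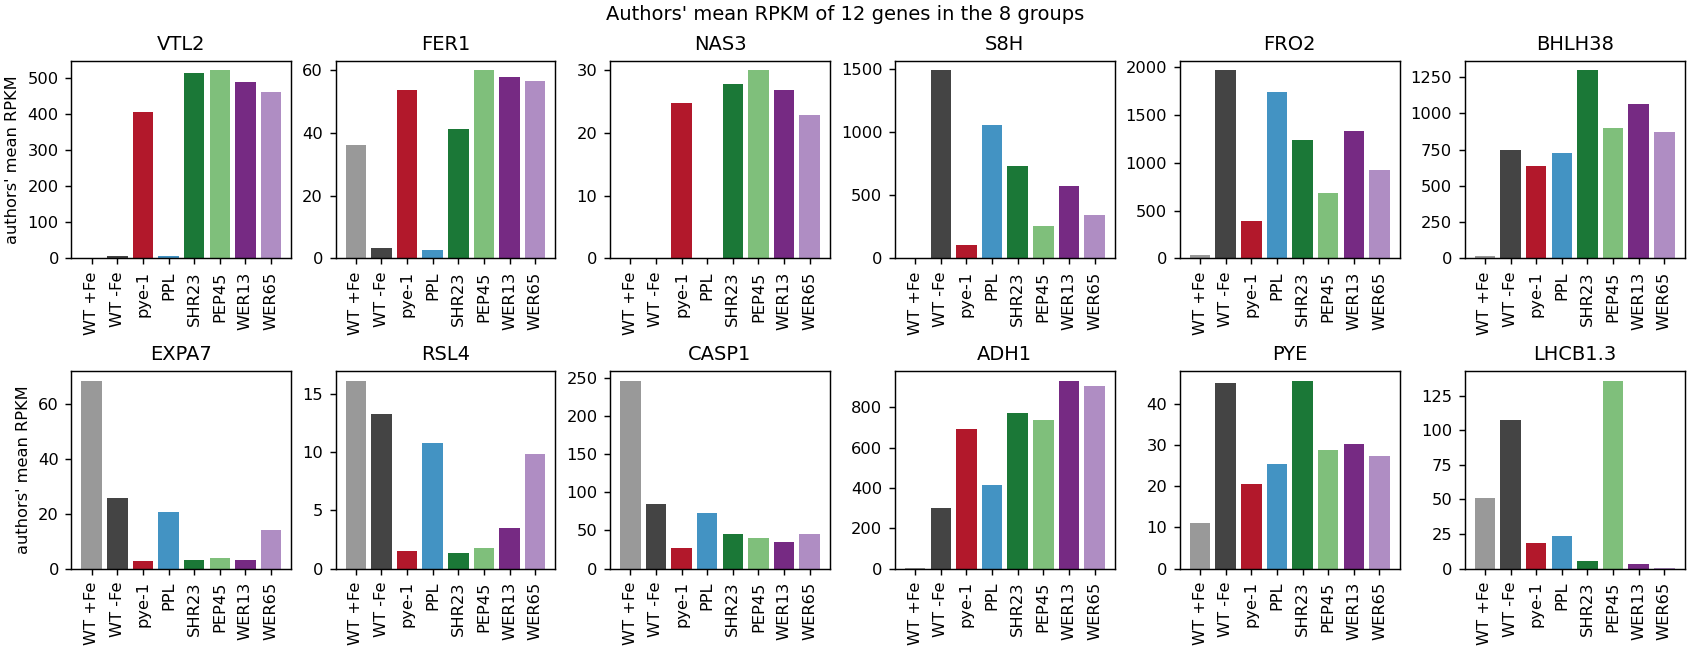
Authors' mean RPKM of 12 genes (vertical axes, each from 0) in the 8 groups (horizontal axes), with 1 bar per group and no error bars because only group means were deposited. VTL2 stood at 5.96 in iron-deficient wild type and 5.58 in PPL, against 404 in pye-1 and 460.4 to 519 in SHR23, PEP45, WER13 and WER65.

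The first comparison asked how wild-type roots responded to iron deficiency. The machinery for taking iron up was strongly induced: 17 of 17 measured uptake genes rose in the authors' deposited table, with a median log2 difference of 4.02. S8H (AT3G12900), which makes the iron-mobilizing coumarin fraxetin, rose from 0.9988 to 1492 RPKM, the largest rise of all listed genes by the log2 scale used (chromosome 3, 4104463 to 4106341). FRO2 (AT1G01580), the root ferric chelate reductase, rose 49.6-fold, and IRT1 (AT4G19690), the main ferrous iron importer, rose 16.3-fold to 3853. Further rises were those of CYP82C4 (AT4G31940) from 6.79 to 1016, an enzyme that converts fraxetin to sideretin, BGLU42 (AT5G36890) from 8.22 to 159, a beta-glucosidase that releases coumarins, MYB72 (AT1G56160) from 0.146 to 37.7, a transcription factor of the same response, and ZIP8 (AT5G45105) from 0.474 to 97.6, a metal transporter of the ZIP family.

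Regulators of iron homeostasis moved with them, 10 of 19 measured genes rising and 3 falling in the authors' deposited table. The basic helix-loop-helix genes BHLH38 (AT3G56970), BHLH39 (AT3G56980), BHLH100 (AT2G41240) and BHLH101 (AT5G04150) rose 41.4-fold, 13.8-fold, 105-fold and 20.5-fold. The small peptide gene IMA1 (AT2G30766) rose from 0.215 to 22.2, and the E3 ubiquitin ligase gene BTS (AT3G18290) rose 7.69-fold. Of 16 genes of iron movement inside the plant, 8 rose in the authors' deposited table, among them NRAMP4 (AT5G67330) from 31.2 to 184, an exporter of vacuolar iron, the nicotianamine synthases NAS1 (AT5G04950) from 26.2 to 207 and NAS4 (AT1G56430) from 7.43 to 119, the nicotianamine transporter ZIF1 (AT5G13740) from 23.5 to 191, and the ferric reductase FRO3 (AT1G23020) from 44.7 to 367. Storage went the other way: 6 of 9 ferritin, vacuolar iron transporter-like (VTL) and NEET genes fell in the authors' deposited table and 1, VTL2 (AT1G76800), rose. The ferritins FER1 (AT5G01600) from 36.2 to 3.34 and FER4 (AT2G40300) from 11.6 to 1.11 fell with VTL5 (AT3G25190) from 96.4 to 8.67 and VTL1 (AT1G21140) from 6.43 to 0.18. Of the 8 genes reported as PYE targets in earlier work, all of which are also members of the transport or storage lists, 4 rose and 3 fell in the authors' deposited table.

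Genes of low-oxygen metabolism rose as a group, 11 of 12 in the authors' deposited table with a median log2 difference of 4.22. ADH1 (AT1G77120), alcohol dehydrogenase, rose from 2.48 to 299, PDC1 (AT4G33070), pyruvate decarboxylase, from 5.51 to 97.2, SUS4 (AT3G43190), sucrose synthase, from 1.77 to 64.4, and PCO1 (AT5G15120), a plant cysteine oxidase, from 1.37 to 140.4. In the root hair list 10 of 15 members fell in the authors' deposited table, including the expansins EXPA7 (AT1G12560) from 68.6 to 25.9 and EXPA18 (AT1G62980) from 43.8 to 11.7 and the proline-rich protein gene PRP3 (AT3G62680) from 138 to 32.6. The Casparian strip genes fell in 6 of 7 cases in the authors' deposited table, CASP1 (AT2G36100) from 246 to 84.8 and CASP5 (AT5G15290) from 80.2 to 16.2, and xylem genes in 8 of 9, such as the laccase gene LAC4 (AT2G38080) from 46.8 to 20.8 and the peptidase gene XCP2 (AT1G20850) from 151 to 67.2. Suberin genes rose in 4 of 13 cases in the authors' deposited table, CYP86A1 (AT5G58860), a fatty acid hydroxylase, among them, from 57.8 to 113.

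Redox genes split, with 2 of 9 rising and 3 falling in the authors' deposited table; the iron-containing enzymes CAT2 (AT4G35090) (catalase), APX1 (AT1G07890) (ascorbate peroxidase) and FSD1 (AT4G25100) (iron superoxide dismutase) fell 4.95-fold, 1.96-fold and 4.78-fold. Zinc and copper genes had 2 rises and 5 falls among 15 in the authors' deposited table, with the ZIP-family gene ZIP9 (AT4G33020) from 2.6 to 31.3 rising and ZIP3 (AT2G32270) from 48.9 to 5.15 falling. The largest falls of single genes included SWEET11 (AT3G48740) from 480.2 to 23.7, a sucrose transporter, and RAP2.6 (AT1G43160) from 50.3 to 1.46, a transcription factor. None of the 20 photosynthesis transcripts, counted as markers of green tissue, was listed, and their median was 15.6 RPKM on iron and 13.7 without. Of 11 core clock genes, a list chosen after their values were seen, the authors' deposited table listed 4 of 4 morning and 4 of 7 later genes as lower. In all, the authors' deposited table listed 4414 genes, 2060 higher and 2354 lower without iron; 2296 of them differed at least 2-fold on the log2(RPKM + 0.5) scale, and 2916 had a mean RPKM of 5 or more. Of the 2296, 54.1% were higher without iron, and of the 2916, 51.4%, so the balance of rises and falls depended on the cut. The q-values rest on the authors' test, which the sources used here do not describe.

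**Figure D2:**
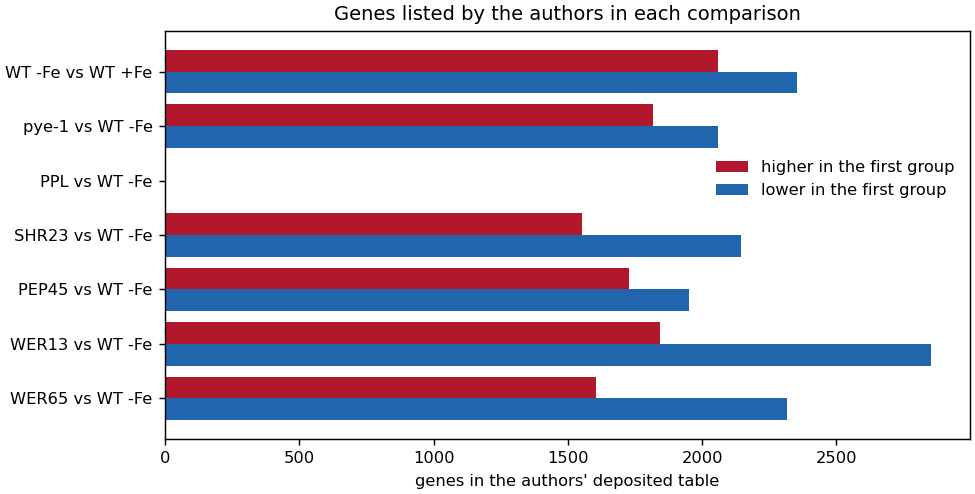
Number of genes in each of the authors' 7 deposited comparison tables (horizontal axis, genes), split into those higher (red) and lower (blue) in the group named first. PPL had 3 genes, pye-1 3878 and WER13, the longest, 4696.

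The comparison of pye-1 with iron-deficient wild type asked what the mutation changed. Iron storage rose and iron uptake fell. All 9 measured storage genes rose in the authors' deposited table, with a median log2 difference of 3.73: VTL2 (chromosome 1, 28829243 to 28830278) from 5.96 to 404 RPKM, VTL1 from 0.18 to 39.6, VTL5 from 8.67 to 121 and FER1 from 3.34 to 53.5. Of 17 uptake genes 16 fell in the authors' deposited table, with a median log2 difference of -1.88; FRO2 fell 5.02-fold, S8H 13.9-fold, IRT1 3.23-fold, BGLU42 7.78-fold, and IREG2 (AT5G03570), a vacuolar metal transporter, 4.49-fold. All 16 of these uptake genes had risen in iron-deficient wild type, and the 6 storage genes that had fallen there rose in pye-1, while VTL2 rose in both comparisons.

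Regulators changed less uniformly, 2 of 19 rising and 4 falling in the authors' deposited table. BHLH38, BHLH39, BHLH100 and BHLH101 were not listed, at 639, 642, 618 and 164 RPKM against 744, 763, 759 and 195 in wild type. The E3 ligase gene BTSL2 (AT1G18910) from 67.7 to 25.6 fell, while IMA1 rose from 22.2 to 46.3, as did BHLH11 (AT4G36060) from 0.587 to 6.65, which encodes a repressor of the iron response. Transport genes also parted, with 6 of 16 rising and 3 falling in the authors' deposited table. NAS3 (AT1G09240) (nicotianamine synthase, chromosome 1, 2984829 to 2986231) was listed at 0 in both wild-type groups and at 24.8 in pye-1, the efflux transporter gene FRD3 (AT3G08040) from 107 to 234 rose, and NAS1 fell from 207 to 36.3. NAS4 (142), ZIF1 (194), FRO3 (395) and BTS (195) were not listed. Of the 8 reported targets 5 rose in the authors' deposited table, each of them a storage gene and so already counted.

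Root hair genes had the lowest median of the lists fixed beforehand, a log2 difference of -2.62, and 13 of 15 fell in the authors' deposited table. EXPA7 fell from 25.9 to 2.88, LRX1 (AT1G12040), a cell wall extensin gene, from 13.5 to 1.15, and RSL4 (AT1G27740), a transcription factor that promotes hair growth, from 13.3 to 1.49. Casparian strip genes fell in 6 of 7 cases in the authors' deposited table, CASP5 from 16.2 to 4.78 and CASP2 from 28.7 to 11.1, and suberin genes rose in 9 of 13, CYP86A1 from 113 to 220.3 and GPAT5 (AT3G11430), an acyltransferase, from 22.4 to 46.6. Low-oxygen genes rose further, 11 of 12 in the authors' deposited table, PDC1 from 97.2 to 355 and ADH1 from 299 to 693. Redox genes rose in 6 of 9 cases in the authors' deposited table, FSD1 from 23.6 to 135 and APX1 from 181 to 434, and ZIP9 fell from 31.3 to 2.88 among the 4 of 15 zinc and copper genes that did so in the authors' deposited table. Other large changes were the rises of ENH1 (AT5G17170) from 0.445 to 43.3, a rubredoxin-like protein gene, and NRT2:1 (AT1G08090) from 0.724 to 50.4, a nitrate transporter, and the fall of CYP71B5 (AT3G53280) from 54.8 to 1.42, a cytochrome P450 gene.

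The photosynthesis transcripts had a median of 4.36 RPKM in pye-1 against 13.7 in wild type, and none of the 20 was listed. The authors' deposited table listed 2 of the 11 core clock genes. In total the authors' deposited table held 3878 genes, 1818 higher and 2060 lower in pye-1. Of these, 1550 differed at least 2-fold and 2451 had a mean RPKM of 5 or more.

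PPL, the line with the widest GFP localization code, was compared with wild type next, and it lay close to it. The authors' deposited table listed 3 genes: PYE, which fell (q = 0.0178), CNGC12 (AT2G46450), a cyclic nucleotide-gated channel gene that rose from 0.794 to 4.39 RPKM (q = 0.00296), and MRD1 (AT1G53480), which fell from 1.96 to 0.0457 (q = 0.0452). MRD1 was named after its values were seen, since the rule for named genes asks for at least 2 RPKM. Storage genes lay near wild type, with VTL2 at 5.58 and FER1 at 2.79 RPKM and a median log2 difference of -0.09, and NAS3 stood at 0.117. IRT1 stood at 3186, FRO2 at 1739.8, BHLH38 at 729.7 and S8H at 1062, none of them listed.

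Some lists nevertheless leaned one way in PPL without any listed member. All 17 uptake genes were lower by value, with a median log2 difference of -0.27, as were 14 of 15 root hair genes, with a median of -0.43, and 12 of 12 low-oxygen genes were higher, with a median of 0.45. All 20 photosynthesis transcripts were lower by value, with a median of 5.29 RPKM against 13.7. The tables hold only genes under a q of 0.05, so neither unadjusted counts nor counts adjusted over the list alone can be given for any comparison. At a mean RPKM of 5 or more, 1 of the 3 genes was left. Whether the lines differ from each other in such counts was not tested.

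SHR23, with the localization code V-EN, had raised storage genes. All 9 storage genes rose against wild type in the authors' deposited table, with a median log2 difference of 3.44, VTL2 from 5.96 to 511, FER1 from 3.34 to 41.3 and NEET (AT5G51720), an iron-sulfur protein gene, from 0.0365 to 16.7 RPKM. Of 19 regulators 11 rose and 1 fell in the authors' deposited table, the risen ones including BHLH38 from 744 to 1296, BHLH39 from 763 to 1148, BHLH100 from 759 to 1510.4, BHLH101 from 195 to 343, IMA1 from 22.2 to 89.8 and BTS from 138 to 289.9. Transport genes rose in 9 of 16 cases in the authors' deposited table, including NAS4 from 119 to 262, ZIF1 from 191 to 428, FRO3 from 367 to 738 and NRAMP4 from 184 to 517. All 8 reported targets rose in the authors' deposited table; they are members of the storage and transport lists. Uptake genes fell in 14 of 17 cases in the authors' deposited table, BGLU42 from 159 to 56.7, FIT (AT2G28160) from 239.8 to 91.7, a transcription factor of the uptake genes, and FRO2 from 1966 to 1238, but IRT1 was not listed, at 3430.4 against 3853.

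Root hair genes fell in 13 of 15 cases in the authors' deposited table, RSL4 from 13.3 to 1.31 and COBL9 (AT5G49270), a cell wall gene of hairs, from 4.34 to 0.837, with a median log2 difference of -2.24. Casparian strip genes fell in 4 of 7 cases in the authors' deposited table, suberin genes rose in 3 of 13, redox genes in 6 of 9, and low-oxygen genes in 12 of 12, such as SUS4 from 64.4 to 269.7 and LBD41 (AT3G02550), a transcription factor, from 98.7 to 324. Zinc and copper genes had 1 rise and 3 falls among 15 in the authors' deposited table, ZIP9 falling from 31.3 to 7.48. Random lists matched to them held a median of 3 listed genes. The largest single rise was that of AT3G01345, from 0.0973 to 81.8, and its next highest group was WER65 at 0.154. Of the 11 core clock genes the authors' deposited table listed 9, the morning gene RVE8 (AT3G09600) from 2.15 to 9.68 rising and PRR7 (AT5G02810) from 21.5 to 4.25, which peaks later in the day, falling. The photosynthesis transcripts had a median of 1.95 RPKM, and 2 of 20 fell in the authors' deposited table, where matched random lists held a median of 4 listed genes. In total 3697 genes were in the authors' deposited table, 1552 higher and 2145 lower. At least 2-fold differences were found for 1539 of them, and 2271 had a mean RPKM of 5 or more.

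PEP45, with the code C-EN-V, also had raised storage and lowered uptake genes. Storage genes rose in 9 of 9 cases in the authors' deposited table, with a median log2 difference of 3.82, VTL2 from 5.96 to 519, VTL1 from 0.18 to 35.9 and NEET from 0.0365 to 29.9 RPKM, and NAS3, listed at 0 in wild type, stood at 29.9. Uptake genes fell in 15 of 17 cases in the authors' deposited table, with a median of -1.53, including IRT1 from 3853 to 2141, FRO2 from 1966 to 682, FIT from 239.8 to 76 and CYP82C4 from 1016 to 170.0. Regulators had 5 rises and 2 falls among 19 in the authors' deposited table, IMA1 rising from 22.2 to 60.8 and BTS from 138 to 217, while BHLH38 (899), BHLH39 (840.5), BHLH100 (906) and BHLH101 (227) were not listed. Transport genes rose in 7 and fell in 3 of 16 cases in the authors' deposited table, FRD3 rising from 107 to 256, NAS4 from 119 to 179.5 and NAS1 falling from 207 to 49. Of the reported targets, 6 of 8 rose in the authors' deposited table.

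Root hair genes fell in 13 of 15 cases in the authors' deposited table, with a median log2 difference of -2.03, EXPA7 from 25.9 to 3.93 and RBOHC (AT5G51060), an NADPH oxidase gene, from 15.47 to 6.21. Casparian strip genes fell in 6 of 7 cases in the authors' deposited table, suberin genes rose in 9 of 13, such as CYP86B1 (AT5G23190) from 22.5 to 55.7, low-oxygen genes in 12 of 12, such as SUS1 (AT5G20830) from 20 to 115, and redox genes rose in 6 of 9 with 1 falling. ZIP9 fell from 31.3 to 5.73, 1 of 3 falling zinc and copper genes of 15 in the authors' deposited table. Random lists matched to this list held a median of 3 listed genes. The largest falls included CYP71B5 from 54.8 to 3.78 and TPS13 (AT4G13300) from 24 to 2.31, a terpene synthase gene, and the calmodulin-like gene CML38 (AT1G76650) from 2.5 to 61.5 was among the largest rises. The photosynthesis transcripts had a median of 13.5 RPKM, against 13.7 in wild type, with none of 20 listed, and the authors' deposited table listed 4 of the 11 core clock genes. The authors' deposited table held 3678 genes for PEP45, 1727 higher and 1951 lower. Of those, 1438 differed at least 2-fold and 2369 had a mean RPKM of 5 or more.

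WER13, with the code EP-C, had the longest list of the 7. All 9 storage genes rose in the authors' deposited table, with a median log2 difference of 3.93, VTL2 from 5.96 to 486, VTL1 from 0.18 to 30.4 and FER1 from 3.34 to 57.9 RPKM, and NAS3 stood at 26.8. Uptake genes fell in 11 of 17 cases in the authors' deposited table, 16 of them being lower by value, S8H from 1492 to 572, FIT from 239.8 to 109 and MYB72 from 37.7 to 17.1. IRT1 at 3372 and FRO2 at 1331 were not listed. Regulators rose in 5 and fell in 1 of 19 cases in the authors' deposited table, IMA1 rising from 22.2 to 84.1, BTS from 138 to 244 and BHLH11 from 0.587 to 7.04; BHLH38 (1067), BHLH39 (965), BHLH100 (1033) and BHLH101 (226) were not listed. Transport genes rose in 8 and fell in 3 of 16 cases in the authors' deposited table, NRAMP4 rising from 184 to 404 and FRO3 from 367 to 606, and 7 of 8 reported targets rose.

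Root hair genes fell in 13 of 15 cases in the authors' deposited table, with a median log2 difference of -2.20, EXPA7 from 25.9 to 3.11, EXPA18 from 11.7 to 1.64 and PRP3 from 32.6 to 6.7. Casparian strip genes fell in 4 of 7 cases in the authors' deposited table, CASP5 from 16.2 to 3.8, while suberin genes rose in 8 of 13, redox genes in 5 of 9 and low-oxygen genes in 12 of 12, HRE2 (AT2G47520), a transcription factor of that response, from 26.1 to 69.5. Xylem genes rose in 3 of 9 cases in the authors' deposited table, LAC4 from 20.8 to 34, and 5 of 15 zinc and copper genes fell. The aquaporin gene TIP2;3 (AT5G47450) from 113 to 3.62 had the largest fall. Of the 11 core clock genes the authors' deposited table listed 9, LHY (AT1G01060) from 0.336 to 2.65, a morning gene, rising and FKF1 (AT1G68050) from 19.4 to 4.31, a later one, falling. The photosynthesis transcripts had a median of 0.739 RPKM, and 6 of 20 fell in the authors' deposited table, LHCB3 (AT5G54270) from 8.67 to 0.079 among them. Random lists matched to these transcripts also held a median of 6 listed genes, so the list did not stand out by this count. All told, 4696 genes were in the authors' deposited table, 1842 higher and 2854 lower. Of these, 1991 differed at least 2-fold and 2948 had a mean RPKM of 5 or more.

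WER65, with the code EP, also had raised storage, 9 of 9 genes rising in the authors' deposited table with a median log2 difference of 3.89, VTL2 from 5.96 to 460.4, VTL5 from 8.67 to 160.4 and FER1 from 3.34 to 56.5 RPKM, and NAS3 stood at 22.7. Uptake genes fell in 15 of 17 cases in the authors' deposited table, with a median of -1.09, S8H from 1492 to 348, FRO2 from 1966 to 924 and IRT2 (AT4G19680), a relative of IRT1, from 135 to 55.1. IRT1 fell from 3853 to 2232, a direction that turned into a log2 difference of 0.16 under quantile normalization. Regulators rose in 3 and fell in 1 of 19 cases in the authors' deposited table, IMA1 rising from 22.2 to 53 and BTSL2 falling from 67.7 to 38.8, and transport genes rose in 6 and fell in 2 of 16, FRD3 rising from 107 to 287. Random lists matched to the regulators held a median of 4 listed genes. BHLH38 (872), BHLH39 (826), NAS4 (163), ZIF1 (214) and FRO3 (488) were not listed, and 5 of 8 reported targets rose in the authors' deposited table.

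Root hair genes fell in 5 of 15 cases in the authors' deposited table, with a median log2 difference of -0.61; EXPA7 fell from 25.9 to 14.1, while RSL4 at 9.84 and PRP3 at 21.2 were not listed. Casparian strip genes fell in 4 of 7 cases in the authors' deposited table, suberin genes rose in 7 of 13, redox genes in 5 of 9 and low-oxygen genes in 11 of 12, with 4 of 15 zinc and copper genes falling. Among the largest rises were AT5G15360 from 0.61 to 77.1 and AT2G01422 from 0.60 to 72.8. Of the 11 core clock genes the authors' deposited table listed 8, LHY rising from 0.336 to 2.17 and FKF1 falling from 19.4 to 5.39. The photosynthesis transcripts had a median of 0.627 RPKM, and 11 of 20 fell in the authors' deposited table, including LHCA4 (AT3G47470) from 39.7 to 2.78 and RBCS1A (AT1G67090) from 62.6 to 3.33; RBCS and LHCB1 copies are near-identical, so reads can be split between them. Random lists matched to the photosynthesis transcripts held a median of 5 listed genes. The total in the authors' deposited table was 3919 genes, 1604 higher and 2315 lower. At least 2-fold differences were found for 1620, and 2531 had a mean RPKM of 5 or more.

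**Figure D3:**
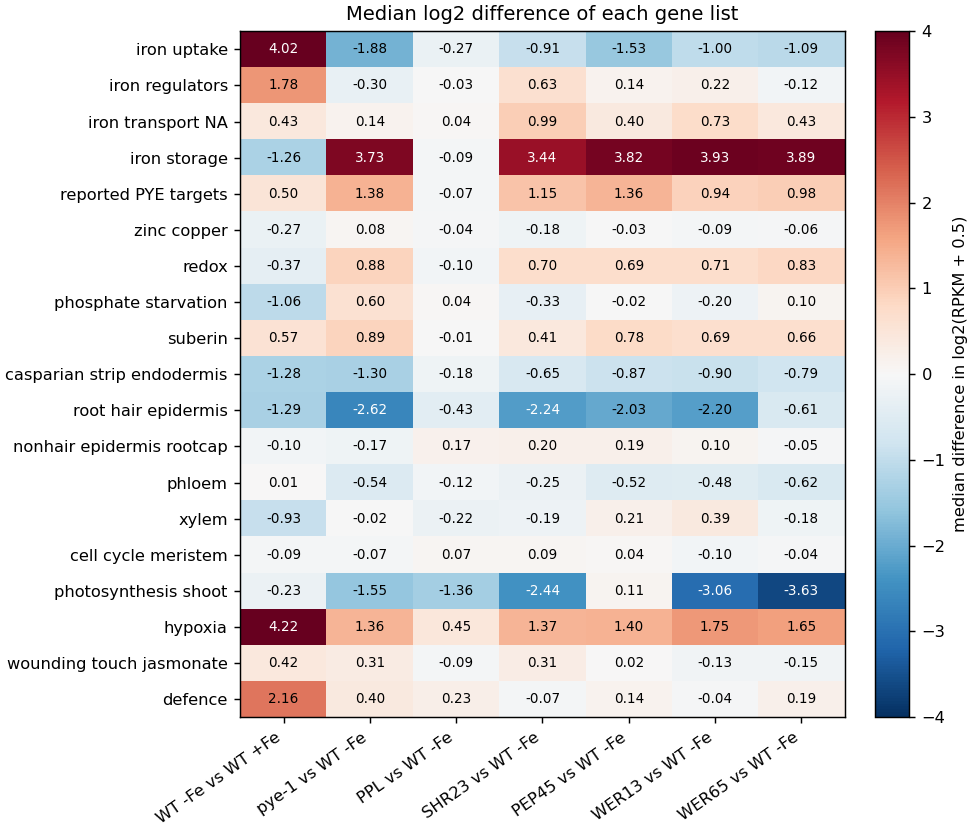
Median log2 difference in RPKM + 0.5 of 19 gene lists (vertical axis) in the 7 comparisons with a deposited table (horizontal axis), from blue (lower in the group named first) to red (higher), with the colour scale ending at 4 in either direction. Iron storage stood between 3.44 and 3.93 in pye-1, SHR23, PEP45, WER13 and WER65 and at -0.09 in PPL, and root hair genes stood at -0.61 in WER65 against -2.20 in WER13.

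How much of the pye-1 change each line shared was asked over the 3766 kept genes listed for pye-1, whose median log2 change, signed by direction, was 0.89 in pye-1 itself. The signed median was 0.15 in PPL, 0.65 in SHR23, 0.79 in WER65, 0.80 in PEP45 and 0.86 in WER13. By the authors' deposited tables, 2732 of these genes were listed in the same direction for WER13, 2689 for PEP45, 2576 for WER65, 2041 for SHR23 and 2 for PPL, and 18, 0, 7, 43 and 0 in the opposite direction. Genes listed as higher in pye-1 and all 4 of SHR23, PEP45, WER13 and WER65 numbered 719, among them VTL2, FER1, FRD3, ADH1 and PDC1, and 843 were lower in all 5, among them S8H, CYP82C4, FIT, EXPA7 and CASP1, by the authors' deposited tables. In opposite directions in a pair of these 5 tables were 93 genes by the authors' deposited tables.

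These comparisons share the iron-deficient wild-type libraries, which alone makes their differences resemble each other. Over all 19767 kept genes the correlation with the pye-1 differences was 0.47 in PPL, 0.75 in SHR23, 0.83 in WER65, 0.84 in WER13 and 0.88 in PEP45, and it is across genes, which are not independent replicates. A pair of unchanged groups sharing a control gave 0.50 when simulated, but pye-1 was not unchanged; at the observed variances the simulated shared covariance alone amounts to a correlation of 0.10 in PPL and 0.04 in the other 4 lines. The simulated noise left out the tails of the PPL differences, whose full variance was 0.0596, so the shared part can be larger. The covariance was 0.0716 in PPL, 0.287 in SHR23, 0.32 in PEP45, 0.333 in WER65 and 0.358 in WER13, against 0.0151 simulated. Of the pye-1 genes 79.2% had the same sign in PPL, 92.3% in SHR23, 97.2% in WER13, 98.2% in WER65 and 99.2% in PEP45, against 66.7% simulated for a pair of unchanged groups. The simulated share covers all genes, not those listed for a changed pye-1, so it is not the expectation for this set. Independent lists would share 133 higher genes between SHR23 and pye-1, where the authors' deposited tables shared 850, and 148, 158 and 138 for PEP45, WER13 and WER65, where they shared 1243, 1210 and 1192. For lower genes independent lists would share 212, 194, 284 and 230.4 in that order, where the authors' deposited tables shared 1191, 1446, 1522 and 1384. With 3 control libraries, pooled into a mean, the controls could not be split, so part of the excess can come from the shared controls.

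**Figure D4:**
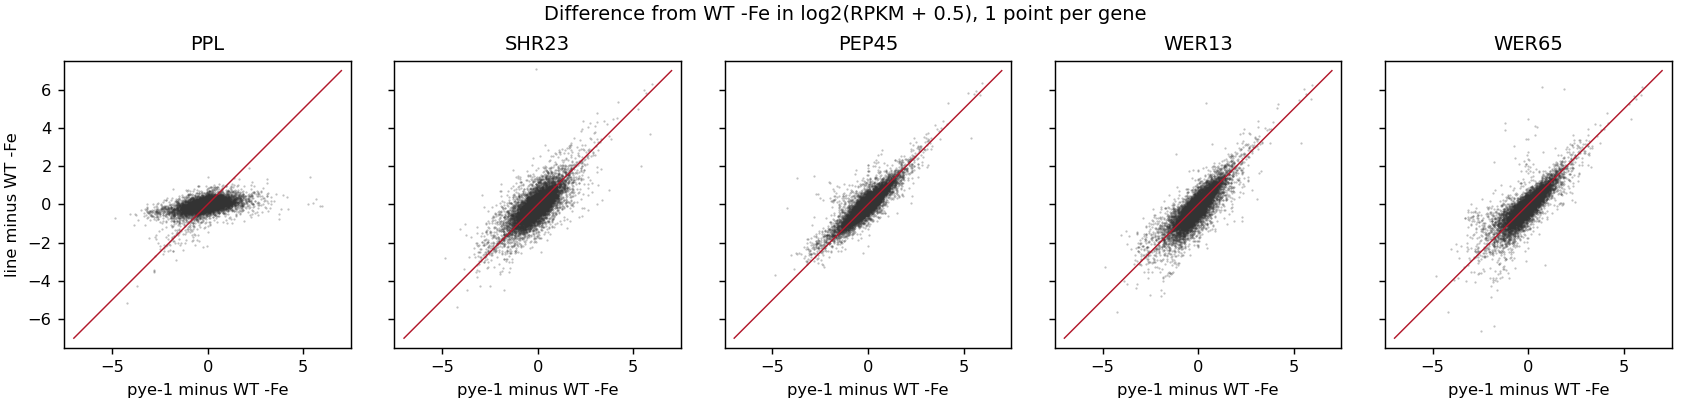
Difference from iron-deficient wild type in log2(RPKM + 0.5) of each line (vertical axes) against that of pye-1 (horizontal axes), 1 point for each of 19767 genes, with the line of equal difference in red. The correlation across genes was 0.47 in PPL and 0.88 in PEP45, the lowest and highest of the 5 lines, and the covariance was 0.0716 and 0.32, against 0.0151 simulated for a shared control alone.

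The lines were then set against pye-1 directly. No authors' table covers these pairs, so genes are counted where the authors' means differed at least 2-fold on the log2(RPKM + 0.5) scale, a rule of size with no test; PPL against wild type, with 3 listed genes, gave 125 such genes, 12 higher and 113 lower. PPL differed from pye-1 in 1314 genes, 735 higher and 579 lower. Storage genes were lower in PPL in all 9 cases, with a median log2 difference of -4.04, VTL2 at 5.58 against 404 RPKM and ENH1 at 0.512 against 43.3. Uptake genes were higher in all 17 cases, with a median of 1.56, S8H at 1062 against 107, CYP82C4 at 839 against 89.4 and IRT1 at 3186 against 1194. Root hair genes were higher in 14 of 15 cases, with a median of 2.08, and low-oxygen genes lower in all 12, with a median of -0.92. At a mean RPKM of 5 or more, 793 genes were left.

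SHR23 differed from pye-1 in 791 genes, 447 higher and 344 lower. Its uptake genes were higher in all 17 cases, with a median log2 difference of 1.24, IRT1 at 3430.4 against 1194 RPKM and FRO2 at 1238 against 392, and its regulators in 16 of 19, with a median of 0.68. Storage genes were lower in 7 of 9 cases, with a median of -0.37. VTL5 was lower, at 14.7 against 121, as was NRT2:1, at 4.43 against 50.4, while BCAT4 (AT3G19710), an aminotransferase of methionine-derived glucosinolate synthesis, was higher, at 86.6 against 9.62. Morning clock genes were higher in all 4 cases and later ones lower in all 7, and photosynthesis transcripts were lower in 17 of 20. At a mean RPKM of 5 or more, 480 genes were left.

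PEP45 was nearest to pye-1 by this count, with 256 genes, 202 higher and 54 lower. Photosynthesis transcripts led the higher genes, CAB3 (AT1G29910) at 45.6 against 0.842 RPKM and LHCB1.1 (AT1G29920) at 23.2 against 0.929, with all 20 of the list higher at a median log2 difference of 1.73. Uptake genes were higher in 16 of 17 cases, with a median of 0.67, IRT1 at 2141 against 1194, and NRT2:1 was lower, at 13.2 against 50.4. The count depended on low values, being 472 with a pseudocount of 0.1, 157 with 1 and 83 at a mean RPKM of 5 or more.

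WER13 differed from pye-1 in 539 genes, 160 higher and 379 lower, and WER65 in 435, 223 higher and 212 lower. Uptake genes were higher in all 17 cases in both lines, with medians of 1.15 in WER13 and 0.84 in WER65, FRO2 at 1331 and 924 against 392 RPKM. Root hair genes were higher in all 15 cases in both, with medians of 0.41 in WER13 and 1.93 in WER65. Storage genes lay near pye-1, with medians of 0.11 and -0.11. AT1G67105 had the largest positive difference in WER13, at 307 against 9.84, and in WER65 it was AT4G16215, at 27.4 against 0.12. Morning clock genes were higher in all 4 cases and later ones lower in all 7 in both lines, and photosynthesis transcripts were lower in all 20. With a pseudocount of 0.1 the counts were 913 and 757, and at a mean RPKM of 5 or more 320 and 201.

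WER13 and WER65, with the codes EP-C and EP, were compared with each other. No other line held either code, so a difference between localizations cannot be told apart from one between these lines. Root hair genes set the lines apart: 14 of 15 were lower in WER13, with a median log2 difference of -1.45, below all 10000 random lists of matched expression, RSL4 at 3.46 against 9.84 RPKM, EXPA7 at 3.11 against 14.1 and PRP3 at 6.7 against 21.2. That rank alone says little, since the same list lay below all random lists in PPL against wild type too, with none of its members listed. Xylem genes were higher in WER13 in all 9 cases, with a median of 0.61, LAC4 at 34 against 22.2, and uptake genes in 15 of 17, with a median of 0.24, IRT1 at 3372 against 2232. Storage genes differed little, with a median of 0.03. By the rule of size 236 genes differed, 60 higher and 176 lower, and none of these differences was tested. The count was 469 with a pseudocount of 0.1 and 97 at a mean RPKM of 5 or more.

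The mean of WER13 and WER65 was also set against the mean of SHR23 and PEP45, which compares these 4 lines and not localizations in general. Root hair genes were higher in the WER lines in all 15 cases, with a median log2 difference of 0.65, a difference carried by WER65, since WER13 stood at 3.05 RPKM by the list's median, SHR23 at 2.96, PEP45 at 2.84 and WER65 at 9.61. Reported targets were lower in 7 of 8 cases, with a median of -0.15, and storage genes had a median of -0.04. Photosynthesis transcripts were lower in all 20, with a median of -2.26, and 5 of 5 shoot transcripts outside photosynthesis were lower with them, with a median of -1.03. The photosynthesis median stood at 13.5 RPKM in PEP45, 1.95 in SHR23, 0.739 in WER13 and 0.627 in WER65, so PEP45 carried most of that difference. By size 285 genes differed, 74 higher and 211 lower. The count was 514 with a pseudocount of 0.1, 179 with 1 and 130 at a mean RPKM of 5 or more.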

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

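Counts under a q-value of 0.01 were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because only group means were analysed, and for the same reason the planned fits on only the compared libraries, with a replicate block, without a variance trend and without each replicate in turn were not run, nor were limma and camera. Among the gene counts, the number of lists standing apart and the carry-over values, 82 alternative values were the same and 28, all of them gene counts, moved over 1.5 times. Where an authors' table existed, genes were not called anew under quantile normalization or centring on the median. Those counts are the listed genes that still differed about 1.5-fold, so they could only fall. A count labelled the same there cannot show whether the authors' calls would hold under another scaling, because no test was repeated. Among single genes and lists, 805 were the same, 97 moved and 1 was reversed. Only a gene listed by the authors could be labelled reversed, and never a list. Several list medians near 0 also changed sign under quantile normalization. Wounding genes in WER13 went from -0.1278 to 0.0699 and defence genes in SHR23 from -0.0713 to 0.0194. So did genes that were not listed, such as BHLH38 in pye-1, from -0.2206 to 0.0186. A 2-fold minimum left 2296 genes in wild type, 1550 genes in pye-1, 1539 genes in SHR23, 1438 genes in PEP45, 1991 genes in WER13 and 1620 genes in WER65, since it asks for more. A mean RPKM of at least 5 left 2916 in wild type, 2451 in pye-1, 1 in PPL, 2271 in SHR23, 2369 in PEP45, 2948 in WER13 and 2531 in WER65, since fewer genes were counted. It left 793 for PPL, 480 for SHR23, 83 for PEP45, 320 for WER13 and 201 for WER65 against pye-1, 97 for WER13 against WER65 and 130 for the WER lines against SHR23 and PEP45. A q-value under 0.01 left 1 gene in PPL. A pseudocount of 0.1 gave 472 for PEP45, 913 for WER13 and 757 for WER65 against pye-1, 469 for WER13 against WER65 and 514 for the WER lines against SHR23 and PEP45; a pseudocount of 1 gave 157 for PEP45 against pye-1 and 179 for the WER lines, as low values weigh more under a small pseudocount. IRT1 in WER65 went from -0.79 to 0.161 under quantile normalization. That setting keeps only the rank of a gene within its group, so the size of the fall in RPKM is lost there. IRT1 in SHR23 and WER13, not listed, also changed sign, from -0.1677 to the same 0.161 and from -0.1923 to 0.4983. Why IRT1 ranked higher in these lines was not tested. Depth limits what low values can show, since a library had at most 24011400 effective reads.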

Other observations

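The core clock list, the second clock list, the list of shoot transcripts outside photosynthesis and all tests on loss of PYE function, on the insertion and on shoot tissue in either wild type were chosen only after the result was seen; the harvest-time test and the shoot-tissue test of PEP45 were written before their results were. Differences between lines in the values that follow were not tested.

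Phosphate starvation genes fell in 3 of 7 cases without iron in the authors' deposited table and rose in 4 in pye-1, the acid phosphatase gene PAP17 (AT3G17790) from 8.3 to 17.9 and SPX1 (AT5G20150), a phosphate sensor gene, from 4.47 to 9.74 RPKM. By the authors' deposited tables, 1 rose and 2 fell in SHR23, 2 and 1 in PEP45, 2 and 2 in WER13, 2 and 1 in WER65, and none in PPL. Of 17 cell cycle genes 4 fell in pye-1 in the authors' deposited table, among them KNOLLE (AT1G08560) from 16 to 10, a syntaxin gene of cell division, with falls in 1, 4, 4 and 3 in SHR23, PEP45, WER13 and WER65 and a rise in 1, 0, 1 and 1. Random lists of matched expression held a median of 4 listed genes in pye-1, and 4, 4, 5 and 4 in those lines. Cell cycle genes did not stand out by this count. The sucrose transporter gene SUC2 (AT1G22710) was the 1 of 6 phloem genes that fell in pye-1 in the authors' deposited table, from 63.1 to 33.1, and it fell to 28.1, 26.2, 15.7 and 23.5 in those lines. Non-hair epidermis and root cap genes had 1 fall of 5 in pye-1 in the authors' deposited table, GL2 (AT1G79840) from 3.43 to 1.93, a transcription factor of non-hair cells. Random lists matched to the phloem or the non-hair list held a median of 1 listed gene in pye-1 as well. Defence genes rose in 5 of 6 cases without iron in the authors' deposited table, CYP71A12 (AT2G30750) from 1.0 to 133, a camalexin enzyme gene, and wounding and jasmonate genes in 6 of 14 with 2 falling; in pye-1 2 defence genes rose, and 3 wounding genes rose and 3 fell. In SHR23, PEP45, WER13 and WER65, 0, 0, 0 and 1 defence genes rose and 2, 1, 2 and 1 fell. CYP71A12 fell in each of these lines, to 52.2, 74, 53.3 and 79.9. Wounding genes rose there in 3, 2, 3 and 2 cases and fell in 3, 4, 3 and 2. All 3 kept cortex genes fell without iron in the authors' deposited table, AT1G62510 from 19.6 to 2.52, CVIF2 (AT5G64620) from 17.5 to 7.41 and AED3 (AT1G09750) from 2.46 to 0.633, and AT1G62510 fell again in pye-1, to 0.533. It also fell in SHR23, PEP45, WER13 and WER65, to 0.449, 0.794, 0.077 and 0.0518. The median of the cortex list was 0.231 RPKM in PPL against 2.52 in iron-deficient wild type, with no cortex gene listed in PPL.

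Some genes were listed in opposite directions in different lines. BCAT4 stood at 24.8 RPKM in iron-deficient wild type, rose to 86.6 in SHR23 and fell to 9.62 in pye-1, 9.19 in PEP45, 6.78 in WER13 and 4.62 in WER65, and JAZ1 (AT1G19180), a jasmonate repressor gene, rose to 111 in SHR23 and fell to 34.5 in PEP45. Other genes were high in particular lines. SADHU3-2 (AT3G42658), a transposable element gene, stood at 55.5 in WER65 against 3.25 in iron-deficient wild type, and AT1G67105 at 307 in WER13 and 127 in WER65 against 7.15. TIP2;3 fell without iron from 1078 to 113 and further, to 28.8 in pye-1, 8.58 in SHR23, 24.4 in PEP45, 3.62 in WER13 and 5.31 in WER65. MRD1 stood at 0.0457 in PPL, 0.052 in PEP45, 0.0358 in WER13 and 0 in WER65, against 1.96 in wild type, 1.93 in pye-1 and 2.77 in SHR23. AT3G47630, which lies before PYE, rose from 9.35 to 40.1 in pye-1 and to between 39.7 and 48.9 in SHR23, PEP45, WER13 and WER65, with 10.5 in PPL, not listed.

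The first pattern weighed was the core clock shift of SHR23, WER13 and WER65, in which the authors' deposited tables listed 9, 9 and 8 of 11 genes against 2 in pye-1 and 4 in PEP45. Harvest at another time of day may give such a shift. In a second list, the median log2 difference from PEP45 of 5 dawn genes less that of 4 dusk genes was 0.03 (0.0292) in SHR23, 0.46 in WER13 and 0.32 in WER65. The bounds were at least 0.5 for a shift and 0.1 or less against it, and neither was met in all 3 lines. The same measure was 0.43 in iron-sufficient and -0.20 in iron-deficient wild type, 0.07 in pye-1 and -0.28 in PPL. Harvest time therefore stays open, and sampling times are not given in the sources used here. Loss of PYE function, to the extent of pye-1, was weighed as the whole cause. All 11 genes lay beyond pye-1 in each line, by a median log2 difference of 0.75 (0.7504) in WER65 and 1.16 in SHR23. Standard errors derived from q in the authors' deposited tables exist only for genes listed for the line. Of these, 8 of 9 in SHR23, 8 of 9 in WER13 and 6 of 8 in WER65 lay over 2 standard errors beyond pye-1. This assumes that pye-1 varied as wild type did. These values go against it as the whole cause but do not exclude it, since the list was chosen after its values were seen. A part in the shift stays open as well, as the median signed change in pye-1 was 0.273 of that in the 3 lines.

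The second pattern was the photosynthesis list, whose median ran from 0.627 RPKM in WER65 to 15.6 in iron-sufficient wild type. Shoot tissue left on some cut roots could raise it in PEP45, where of 5 shoot transcripts outside photosynthesis 4 were higher than in the mean of SHR23, WER13 and WER65, with a median log2 difference of 1.19. The differences ran from -0.01 to 2.46, and none of the 5 was listed for PEP45. By level the median of these 5 did not stand out in PEP45, at 4.00 RPKM against 5.14 in SHR23, 4.00 in WER13 and 3.20 in WER65. The same 5 genes gave -0.01 (-0.00672) for iron-deficient wild type, whose photosynthesis median was 13.7 against 13.5 in PEP45, so its level stays open, and -0.75 (-0.7545) for iron-sufficient wild type, the highest of them 0.14, which goes against shoot tissue there but does not exclude it, since iron supply differed as well and 2 of the 5 genes stood under 1 RPKM in it. The 2 lists also went apart in SHR23 against pye-1, with a median of 0.63 for the shoot transcripts and -1.04 for the photosynthesis list. Against loss of PYE function as the whole cause stood PPL, lower than wild type in 20 of 20 genes by a median log2 difference of -1.36, and PEP45, 1.73 above pye-1, but it stays open, since the authors' deposited tables listed 0 of 20 in PPL, pye-1 and PEP45, and shoot tissue could raise PEP45.

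The third pattern was a pair of genes near the pye-1 level in PPL. CNGC12 rose from 0.794 to 5.31 RPKM in pye-1 and to 4.39 in PPL, 0.885 of the log2 change, a value the gene was picked for, so loss of PYE function stays open for it. AT3G47650 fell from 4.6 to 1.18 in pye-1 and stood at 1.29 in PPL, not listed, 0.945 of the log2 change, and the same holds for it. AT3G47650 starts 29 bases after PYE, so an effect of the insertion on the neighbouring gene is possible but cannot be told apart, because no insertion site, and not whether PPL carries the pye-1 insertion, is given in the sources used here.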
